A study of Mus musculus with 2 samples.

How the data were processed

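RNA was measured in the livers of 2 newborn B6NCrl mice (postnatal day 0), an inbred C57BL/6N strain. Per the labels, each library was made from 1 whole liver, and both pups came from the same dam, so the livers are those of littermates and form 1 group of 2 biological replicates. The sex of the pups was not recorded in the labels. Libraries started from 10 ng of RNA longer than 200 nt, with synthetic ERCC spike-in RNAs added, per the labels' protocols. The labels call the assay total RNA-seq. Their protocols also cite a manual for a low-input cDNA kit whose first strand is primed with oligo-dT, which copies RNAs that carry a poly(A) tail. The labels do not say which reagents of that manual were used, so the priming is treated as open.

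The authors deposited, for each library, a table of genes and a table of transcripts in the layout that the program RSEM writes. The assembly was mm10 and the gene annotation GENCODE M4, per the notes deposited with the files; the aligner, the counter and their versions are not given in the sources used here. Expected counts were deposited by the authors as estimated reads per gene, with reads that match several genes divided among them, so they are not whole numbers. TPM values were deposited by the authors as reads divided by effective length and scaled to a fixed total over all rows of a table. FPKM values were deposited by the authors as reads per kilobase of effective length scaled to the library's reads, and were used here only as an alternative. The deposited transcript tables also give each transcript's percent of its gene's TPM. Effective length was 99 nt less than the length in the table, so rows under 100 nt had an effective length of 0 and could hold no reads. Features only slightly longer than 100 nt have inflated TPM values for the same reason. The authors' credible intervals of TPM cover counting and read assignment; their level is not given in the file headers. They belong to a second, posterior mean estimate, and for very abundant genes the TPM value can lie outside them.

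Each gene table held 69691 rows, of which 43346 were Ensembl genes, 26248 tRNA rows, 96 ERCC spike-ins and 1 the phiX control. Gene symbols, biotypes and coordinates were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, by Ensembl identifier without its version. This matched 42462 Ensembl genes and left 884 without a symbol, which held 0.1% of the expected counts in pup 1 and 0.103% in pup 2. Coordinates below are those of M21 on GRCm38, counted from 1. Total expected counts were 42124582 in the liver of pup 1 and 41443673 in the liver of pup 2. At these depths a count of 0 allows up to 3 counts, or 0.0712 CPM (counts scaled by the library total) in pup 1 and 0.0724 in pup 2. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

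With 1 group there was no contrast between conditions to test. Levels are given as the mean and SD over the 2 livers. A gene counted as detected at a TPM of 1 or more in each liver. Before the data were examined, 47 gene lists and 23 gene pairs were fixed, together with the main analysis of each result, most of the alternatives and the rule for the genes named. For each list the share of TPM, the median TPM and the number of detected members were computed; 7 listed symbols had no match. A log2 ratio within a gene pair was called larger than the replicate spread when both livers lay on the same side of 0 and the mean was over 3 SD from 0. Both genes of a pair were measured in the same 2 livers, and an exact two-sided sign permutation over 2 livers cannot go below a p of 0.5, so no p-value is printed. Shares of expected counts, which weight genes by length as TPM does not, are given beside shares of TPM where they differ by over 1.5 times.

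The livers were compared as pup 2 over pup 1, on log2(TPM + 1), a scale that understates the change of low genes. Genes counted as at least 2-fold apart when the log2 ratio was 1 or more in size, the mean TPM was 1 or more and the authors' credible intervals did not overlap. This is a rule of size that compares 2 animals, each with 1 library, and has no replicate check. For lists with at least 5 members at a mean TPM of 1 or more, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of expression. Its percentile describes these libraries and is not a p-value, since members of a list share regulation and random genes do not. The spread between livers was estimated with edgeR 4.0.16 in R 4.3.3 as the common and trended biological coefficient of variation, from expected counts rounded to whole numbers, TMM factors, genes kept by its expression filter and an intercept-only design. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and matplotlib 3.10.9 for figures.

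The steps were tested on simulated data. For the comparison of the livers, counts were simulated for the 12711 genes at a mean TPM of 1 or more, with 200 genes changed. The simulated coefficient of variation was 0.1 for every gene, and the simulated intervals covered counting error only. The rule of size then called 89% of genes changed 3-fold, 99% of genes changed 8-fold and 0.5% of genes changed 1.5-fold. Among unchanged genes it called 1 beside the 3-fold changes, 0 beside the 8-fold changes and 3 beside the 1.5-fold changes. In the data the trended coefficient of variation was 0.199 at 2 CPM, and the authors' intervals also cover read assignment. The simulation therefore does not show how often low genes are called wrongly in the data. A simulated coefficient of variation of 0.1 came back as 0.1002 over 15569 genes. Of 10 simulated lists of 20 genes, 10 lay outside the middle 95% of random lists at a log2 shift of 0.2, and 0 at a shift of 0.

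Genes named are the 20 of highest mean TPM, up to the 4 highest and 2 lowest members of each list, all genes of the pairs, all members of the lists of RNAs without a poly(A) tail and of X inactivation and Y-linked genes, list members at least 2-fold apart, and the 10 genes farthest apart in each direction at a mean TPM of 5 or more. For transcripts they are the most abundant transcript of the 20 top genes and the 10 genes of highest TPM whose most abundant transcript differed between the livers. Alternatives covered the unit, the detection level, the pseudocount, filters on low values, TMM, median-of-ratios and spike-in scaling, TPM rescaled without globins and mitochondrial genes, the posterior mean estimates, and each liver alone. A correction for effective length and GC content, and a count without the muscle and pancreas lists, were chosen after seeing the data. The phiX row held 0 counts, and no column of another sample was present. Alignments and signal tracks were not used here.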

Results

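The transcriptome of the newborn mouse liver was profiled in 2 littermates on postnatal day 0, giving 42124582 expected counts for pup 1 and 41443673 for pup 2. The labels imply a description of levels in this tissue and of the spread between littermates. A TPM of 1 or more was reached by 12755 Ensembl genes in pup 1 and by 12688 in pup 2, and 12332 genes reached it in both livers. Of the shared genes, 11354 were protein-coding, 120 were long intergenic noncoding RNAs and 395 were pseudogenes. A TPM of 100 or more in both livers was reached by 1046 genes, and a TPM of 1000 or more by 110.

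Globins and secreted hepatocyte proteins dominated the RNA pool. The 10 most abundant genes held 26.9% ± 0.138 of TPM (SD, n = 2) and the 100 most abundant 54.3% ± 0.392. The most abundant gene was Hba-a2 (ENSMUSG00000069917.7, chromosome 11, 32296489 to 32297298), an adult alpha globin, at 58141 ± 805 TPM. It was followed by the adult beta globin Hbb-bs (chromosome 7, 103826534 to 103828096) at 36475 ± 1825 TPM and by Hba-a1 (chromosome 11, 32283511 to 32284465) at 28064 ± 189 TPM. Trf, which encodes the iron carrier transferrin (chromosome 9, 103204001 to 103230444), stood at 27602 ± 3091 TPM. Apoa1, the main protein of high-density lipoprotein (chromosome 9, 46228580 to 46230466), stood at 23974 ± 145 TPM. The fetuin gene Ahsg, the globin Hbb-bt and the apolipoprotein genes Apoa2 and Apoe followed, and albumin (Alb, chromosome 5, 90460897 to 90476602) ranked 10 with 14198 ± 731 TPM. Hba-a1 and Hba-a2, and likewise Hbb-bs and Hbb-bt, are near-identical paralogs, so the division of reads within each pair is uncertain.

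Ranks 11 to 20 held RNAs of other kinds. Rn7s1 and Rn7s2, near-identical copies of the 7SL RNA of the signal recognition particle, were each given 11533 TPM, with reads shared between them. The mitochondrial genes mt-Atp6 (10651 ± 1022 TPM), mt-Atp8 (7746 ± 750 TPM) and mt-Rnr2 (7180 ± 134 TPM) were in this range. So were the unprocessed pseudogenes Gm28437 (9165 TPM) and Gm29216 (5579 TPM) on chromosome 1. They resemble mitochondrial sequence, so the division of reads between these pseudogenes and the mitochondrial genes is uncertain. Alpha-fetoprotein (Afp) at 9945 ± 298 TPM, the retinol carrier Rbp4 at 6807 ± 270 TPM and the fatty acid binding protein Fabp1 at 6231 ± 628 TPM completed the 20 most abundant genes. Protein-coding genes held 90.8% ± 0.137 of TPM.

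The hepatocyte programme was detected broadly. All 27 plasma protein genes were detected and together held 16.3% ± 0.323 of TPM, with 26 of them at 100 TPM or more in both livers. All 16 hepatocyte transcription factors were detected but held 0.0458% ± 0.00205 of TPM (0.0738% of expected counts), led by Ppara at 153 ± 11.1 TPM and Foxa3 at 63.6 ± 13.9 TPM, with Foxa1 lowest at 1.65 ± 0.509 TPM. Of the 26 coagulation and complement genes, 25 were detected, led by antithrombin (Serpinc1) at 2735 ± 55.2 TPM, while the terminal complement component C9 stood at 1.24 ± 0.559 TPM. Of the 18 acute phase and metal response genes, 15 were detected. Haptoglobin (Hp) stood at 3543 ± 47.6 TPM and metallothionein Mt1 at 2891 ± 736 TPM, whereas Saa2 and Orm2 stayed below 1 TPM. Of the 19 genes of metal, vitamin and hormone handling, 17 were detected, with the ferritin genes Ftl1 at 4675 ± 255 and Fth1 at 4610 ± 217 TPM.

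Fetal and adult markers were present side by side. Of the 15 genes of fetal parenchyma, 13 were detected, among them Afp, Igf2 at 1387 ± 89 TPM and the imprinted noncoding RNA H19 at 1299 ± 35.1 TPM. Lin28b and Cdh17 stayed below 1 TPM. Among 26 imprinted genes, 22 were detected. The log2 ratio of Alb to Afp was 0.51 ± 0.12 (SD, n = 2), and that of Igf1 to Igf2 was -5.39 ± 0.30, so the fetal growth factor was 42 times the level of the postnatal one. Of 17 cytochrome P450 genes prominent in adult liver, 15 were detected, led by Cyp4a14 at 837 ± 25.7 TPM and Cyp3a11 at 670 ± 107 TPM. Cyp2c29 (0.275 ± 0.00707 TPM) and Cyp7b1 (0.455 ± 0.0495 TPM) stayed below 1 TPM. The ratio of Cyp3a11 to the perinatal Cyp3a16 was 4.38 ± 0.23 on the log2 scale. Of 17 major urinary protein and other adult secreted genes, 6 were detected in both livers, led by Serpina1e at 3830 ± 157 TPM, and the urinary protein genes Mup2 and Mup7 had 0 counts in both. The Serpina1 and Mup families hold similar copies, so their single values are uncertain. All 18 genes of the growth factor axis were detected, with Igfbp2 at 2969 ± 24.1 TPM and Igf1 at 33.2 ± 4.85 TPM.

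Metabolic genes differed widely in level by pathway. All 21 genes of fatty acid oxidation and ketogenesis were detected, with a median of 255 ± 16.7 TPM. All 21 urea cycle and amino acid genes were detected (median 169 ± 4.02 TPM), led by Bhmt at 1979 ± 52.8 TPM. All 18 gluconeogenesis and glycogen genes were detected (median 78 ± 14.2 TPM), including Fbp1 at 2197 ± 95.2 TPM and the rate-limiting Pck1 at 489 ± 181 TPM. Of 16 glycolytic genes, 15 were detected in both livers, with a median of 147 ± 16.9 TPM. Lipogenic genes were lower, with a median of 10.1 ± 1.62 TPM and 15 of 17 detected. Acetyl-CoA carboxylase Acaca stood at 1.7 ± 0.0141 TPM in that list, and the desaturase Fads2 at 222 ± 10.2 TPM. All 20 cholesterol synthesis genes were detected at a median of 16.9 ± 0.993 TPM. Of 16 bile acid genes, 14 were detected, led by the uptake carrier Slc10a1 at 437 ± 3.41 TPM.

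Gene pairs placed these levels against related forms. Of the 23 pairs, 20 had a ratio larger than the spread between the livers. The log2 ratio was 5.35 ± 0.46 for cytosolic Pck1 over mitochondrial Pck2 and 3.59 ± 0.15 for liver-type Cpt1a over muscle-type Cpt1b. The liver pyruvate kinase gene Pklr lay below the general form Pkm, at -2.28 ± 0.32. The log2 ratio of Cyp8b1 to Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.24 ± 0.68. It was 6.64 ± 0.27 for the deiodinases Dio1 over Dio3, although Dio3 rested on 4 and 3 counts. Ratios were also larger than the spread for Slc2a2 over Slc2a1 (1.87 ± 0.14), Mt2 over Mt1 (-2.53 ± 0.047), Igfbp1 over Igfbp2 (-1.16 ± 0.33), Acaca over Acacb (0.83 ± 0.13) and Lyz2 over Lyz1 (9.90 ± 0.74). Among the ratios that did not exceed the spread were those of Glul to Cps1 (0.028 ± 0.074) and of the Kupffer cell genes Clec4f to Cd5l (0.16 ± 0.065).

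Genes of blood cells and their precursors were prominent. The 4 measured adult globins, whose RNA circulating red cells also carry, held 14.4% ± 0.308 of TPM and 6.3% of expected counts, while embryonic globins held 0.00118% ± 1.27e-05 of TPM and 0.000599% of expected counts. The log2 ratio of Hbb-bs to the embryonic Hbb-y was 12.93 ± 0.11, to Hbb-bh1 14.27 ± 0.41, and that of Hba-a1 to Hba-x 12.38 ± 0.11. All 26 erythroid genes and all 14 heme synthesis genes were detected. Carbonic anhydrase Car2 stood at 822 ± 53.7 TPM, 3.63 ± 0.028 above Car1 on the log2 scale, and erythroid Alas2 at 396 ± 8.96 TPM, 2.41 ± 0.12 above the general Alas1. All 20 neutrophil genes were detected and held 0.989% ± 0.0157 of TPM (0.47% of expected counts), led by S100a8 (4522 ± 119 TPM) and S100a9 (2254 ± 91.4 TPM). All 16 megakaryocyte genes were detected, with Pf4 at 576 ± 3.71 TPM. Stem and progenitor genes were low, with 12 of 15 detected and Spi1 highest at 29.2 ± 2.11 TPM. Of 20 lymphoid genes 15 were detected, led by the pre-B cell gene Vpreb3 at 55.6 ± 2.13 TPM, and Cd3e had 1 count in each liver. Of 14 mast cell, basophil and eosinophil genes, 8 were detected, with Ear2 highest at 30.5 ± 0.17 TPM.

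Genes of other resident cells were also detected. Macrophage and Kupffer cell genes held 0.161% ± 0.00315 of TPM with 21 of 23 detected, among them Lyz2 at 500 ± 11.4 TPM and Clec4f at 66.2 ± 1.85 TPM. All 18 endothelial genes were detected (0.0313% ± 0.00111 of TPM, 0.0605% of expected counts), led by Egfl7 at 45.3 ± 2.1 TPM. Of 21 stellate and mesenchymal genes 18 were detected, with Sparc at 246 ± 13.3 TPM. Of 14 bile duct genes 9 were detected, with Spp1 at 77.4 ± 18.5 TPM, and Krt18 led 7 detected genes of 9 in the mesothelial list at 222 ± 15.5 TPM, although hepatocytes also make Krt18. All 28 cell cycle genes were detected at a median of 48.1 ± 5.72 TPM, led by Ube2c (228 ± 22.3 TPM) and Rrm2 (223 ± 26.5 TPM). Of 19 immediate early and heat shock genes, 13 were detected, with Hspa8 at 651 ± 21.3 TPM. Of 14 clock genes 12 were detected at a median of 5.04 ± 0.0919 TPM. All 15 housekeeping genes were detected, from Actb at 2837 ± 217 TPM to Polr2a at 5.88 ± 0.134 TPM. The plot of list shares sets all lists side by side.

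**Figure D1:**
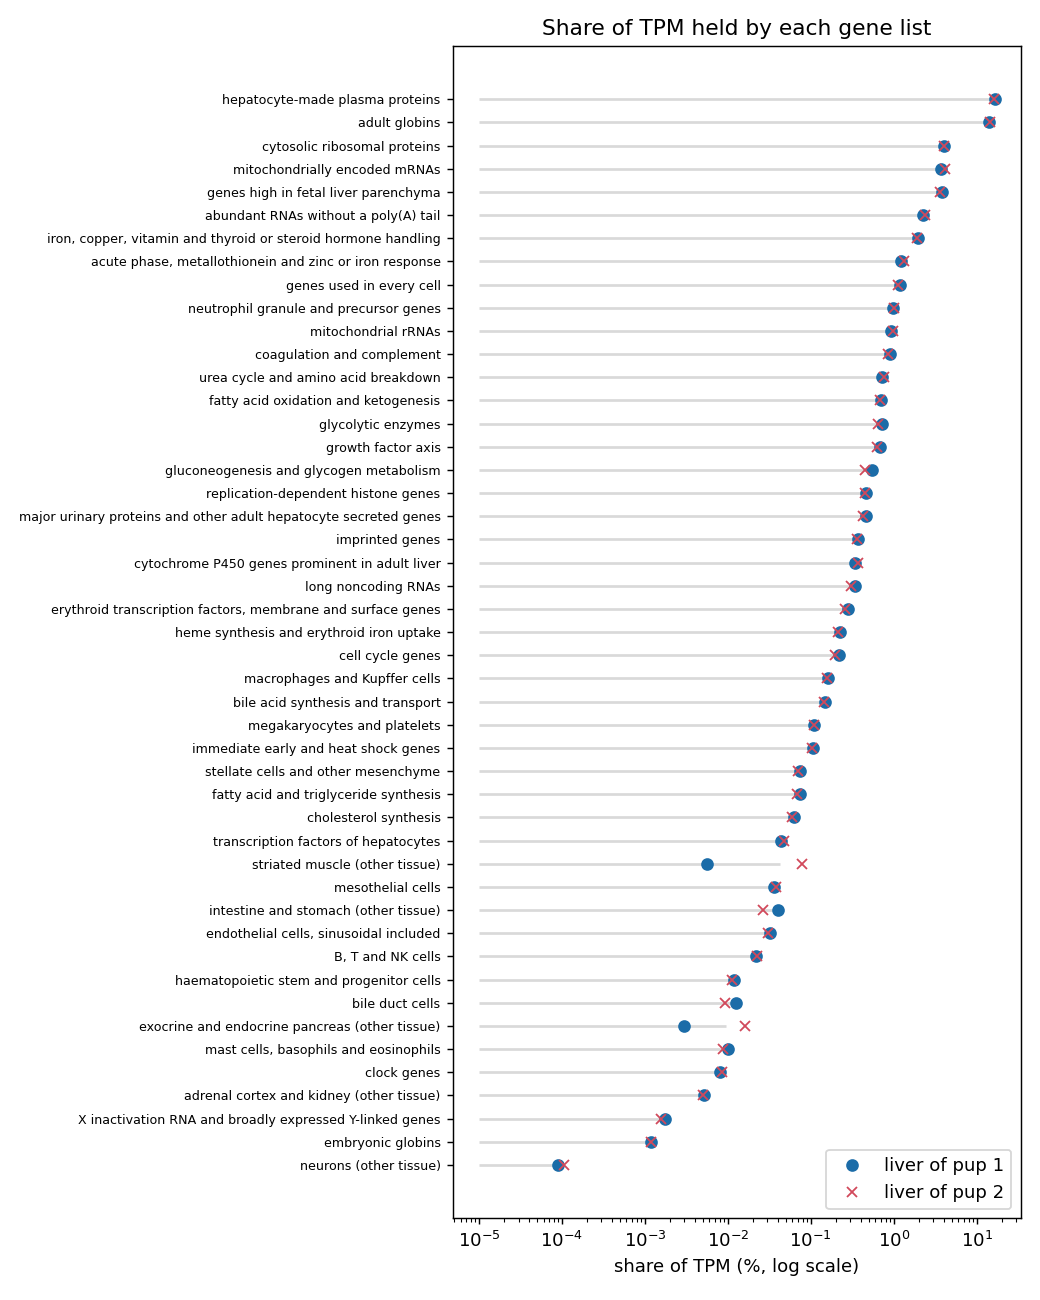
Share of TPM (%, log scale) held by each gene list in the liver of pup 1 (circles) and pup 2 (crosses); grey lines run to the mean. Plasma proteins (16.3%) and adult globins (14.4%) lead, and the gap between the livers is widest in the muscle list (0.00556% and 0.0793%).

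RNAs of the translation machinery and of mitochondria made up a further part of the pool. Of 84 cytosolic ribosomal protein genes 81 were detected, holding 4.04% ± 0.0241 of TPM (1.97% of expected counts), and the 13 mitochondrial mRNAs held 3.97% ± 0.336 (2.32% of expected counts). Reads given to the pseudogenes Gm28437 and Gm29216 may belong to mitochondrial mRNAs. The share of the mitochondrial mRNAs, and the difference of that list between the livers, are uncertain for this reason. The mitochondrial rRNAs held 0.944% ± 0.0383. Among RNAs without a poly(A) tail, Rn7s1 and Rn7s2 were abundant, Rn7sk stood at 169 ± 6.68 TPM and Rpph1, the RNA of ribonuclease P, at 106 ± 0.672 TPM. The others were low or undetected. Scarna2 stood at 3.33 ± 0.177 TPM and Rmrp at 2.6 ± 1.39 TPM, Rnu11, Rny1, Terc and Scarna6 had at most 6 counts in either liver, and Rny3, Rnu12, Rprl1, Rprl2 and Rprl3 had 0 counts in both. The list held 2.33% ± 0.0993 of TPM and 0.402% of expected counts. Of 62 replication-dependent histone genes 46 were detected, led by Hist1h2ap at 3302 ± 17.6 TPM, and the list median was 5.32 ± 0.0884 TPM. Of 16 long noncoding RNAs 14 were detected, with Malat1 at 1444 ± 288 TPM. Xist, expressed from the inactive X chromosome, stood at 17.3 TPM in pup 1 and 15.7 TPM in pup 2. Of the Y-linked genes, Ddx3y and Uty each had 1 count in pup 1 and Kdm5d 1 count in pup 2. Eif2s3y, Usp9y, Zfy1, Zfy2 and Sry had 0 counts in both livers.

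The livers were close to each other across genes. Pearson's r of log2(TPM + 1) was 0.993 and Spearman's rho 0.958 across 23303 genes, which are not independent replicates. The SD of the log2 ratio was 0.36 among genes of 1 to 10 TPM, 0.28 from 10 TPM, 0.19 from 100 TPM and 0.13 from 1000 TPM. The common biological coefficient of variation from edgeR was 0.118 over 15420 genes. Its trended value ran from 0.199 at 2 CPM to 0.0804 at 1024 CPM. The ERCC spike-ins drew 163 counts in pup 1 and 190 in pup 2, or 3.87 CPM (exact 95% binomial interval 3.3 to 4.51) and 4.58 CPM (3.96 to 5.28). Their ratio per depth, 1.18 (0.956 to 1.47), did not differ from 1 beyond counting error, and 13 of 96 spike-ins had counts in both.

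Genes of striated muscle and pancreas stood out between the littermates. In all, 80 of 12711 genes at a mean TPM of 1 or more (0.629%) were at least 2-fold apart. Of these, 72 were higher in pup 2 and 8 lower. Without the muscle and pancreas lists, a count chosen after seeing the data, these were 52 and 8. Most of the 52 were further genes of these tissues that the short lists did not hold. Outside the rule for named genes, they included Tnni2, Atp2a1, Ttn, Neb, Actn2, Mybpc1, Myoz1 and Casq1 of muscle, beside Sln. Of pancreas they included Cel, Sycn and Pnliprp1, beside Clps. The 52 are therefore not a difference apart from muscle and pancreas. Among the 72 were 9 of the 13 muscle genes and 11 of the 20 pancreas genes. Skeletal actin Acta1 (chromosome 8) was at 16.3 TPM in pup 1 and 310 TPM in pup 2, a 19-fold difference (exact counting interval 17.7 to 20.5). The myosin light chain Myl1 was at 5.32 and 134 TPM, troponin Tnnc2 at 5.7 and 111 TPM, and creatine kinase Ckm at 3.44 and 65 TPM. Tnnt3 and the sarcoplasmic regulator Sln differed by 19.8-fold and 19.5-fold. Of the digestive enzymes made by pancreatic acinar cells, chymotrypsinogen Ctrb1 had 3 counts in pup 1 and 947 in pup 2, a ratio of 305 with a counting interval of 107 to 1523. Cela2a was at 0.54 and 25 TPM and colipase Clps at 1.18 and 26.6 TPM. Try5 and the insulin gene Ins2 had 0 counts in pup 1 and stood at 14.6 and 8.92 TPM in pup 2, where the authors' credible intervals in pup 1 reached 0.19 and 1.28 TPM. The trypsinogens Try4, Try5, Try10, Prss1 and Prss2 are similar copies whose single values are uncertain. The pancreas genes Cela1 (17 and 17.3 TPM) and Pnlip (0 counts in both) were level. The intestine, adrenal and kidney, and neuron lists held 2, 1 and 0 genes detected in both livers, and the pancreas list itself held 2. Of 3 genes of the intestine and stomach list at a TPM of 1 or more in a liver, only Reg1 was over 2-fold apart. Reg1 had 3 counts in pup 1 and 40 in pup 2, a ratio of 12.8 with a counting interval of 4.22 to 66.9. As a single member of its list, Reg1 does not tell intestine from another source. The Reg1 mean of 0.9 TPM lay below the 1 TPM needed for the 80 genes. The calcium buffer Pvalb of the adrenal and kidney list, also made by fast muscle, had 2 counts in pup 1 and 64 in pup 2, a ratio of 29.9 with a counting interval of 8.45 to 268. In the mesenchymal list Des was at 3.51 and 12.3 TPM, and in the acute phase list Saa3 at 4.55 and 10.4 TPM. The remaining list members at least 2-fold higher in pup 2 were Mylpf, Myh8, Actc1 and Mb of muscle. Of pancreas they were Cela3b, Cpa1, Ins1 and the trypsinogens Try4, Try10, Prss1 and Prss2.

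**Figure D2:**
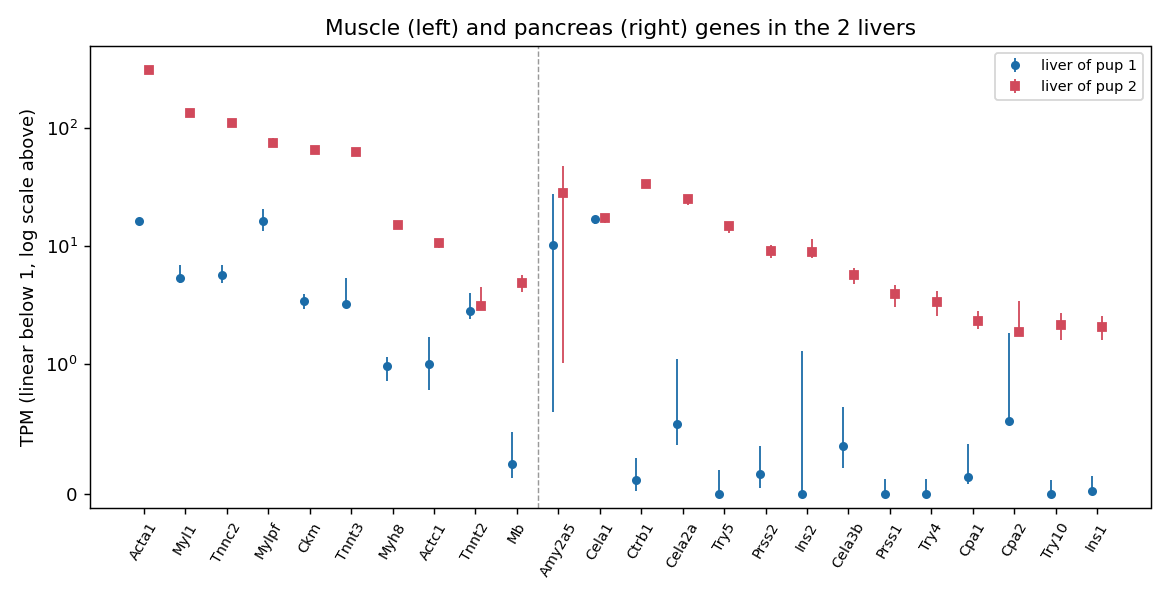
TPM of the muscle and pancreas genes at a mean of 1 or more in the liver of pup 1 (circles) and pup 2 (squares), with the authors' credible intervals as bars; the axis is linear below 1 and logarithmic above. Acta1 is at 16.3 TPM in pup 1 and 310 TPM in pup 2, while Cela1 is level at 17 and 17.3 TPM.

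The genes lower in pup 2 were fewer and the differences smaller. Among the 8 were G6pc, the glucose-6-phosphatase that releases glucose (181 and 85.2 TPM), and Cyp7a1 (37.2 and 17.2 TPM). The phosphatidate phosphatase Lpin1 was at 12 and 3.57 TPM, the transcription factor Klf15 at 37.9 and 18.4 TPM, and the clock gene Per1 at 7.05 and 2.53 TPM. Tsku was at 14.5 and 6.09 TPM and Ankrd37 at 8.11 and 2.59 TPM. Pck1 at 617 and 361 TPM and the intestinal and hepatic apolipoprotein Apoa4 at 370 and 222 TPM did not reach 2-fold. With spike-in scaling the split was 64 higher and 17 lower, and with TMM-scaled counts 72 and 4, in place of 72 and 8.

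**Figure D3:**
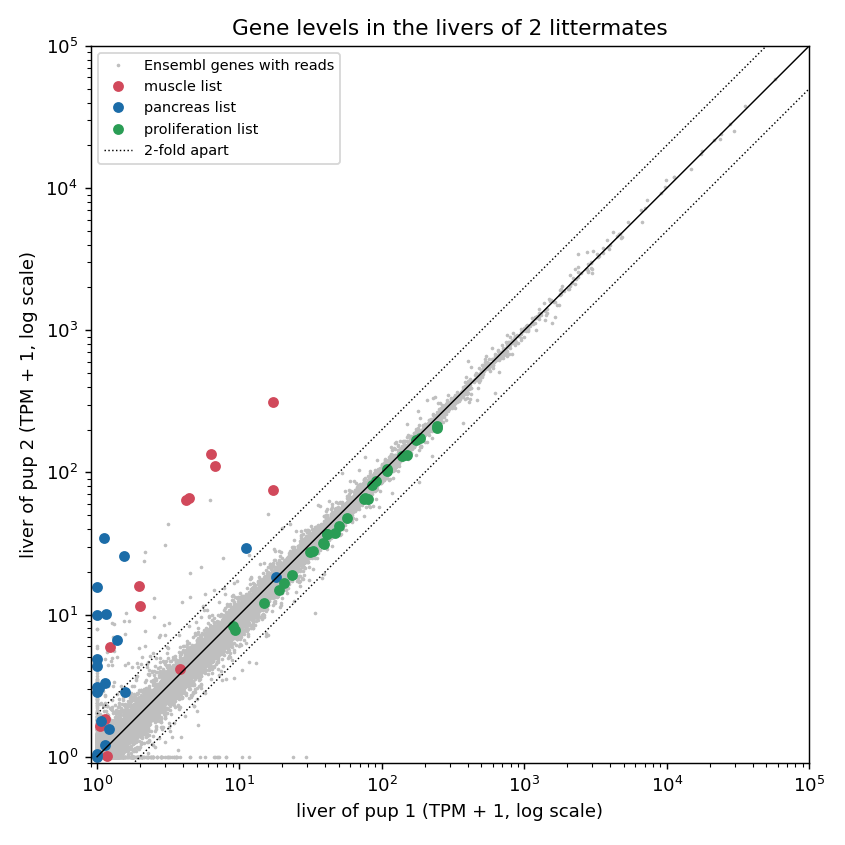
Level of each Ensembl gene with reads in the liver of pup 1 (x axis) and pup 2 (y axis), both as TPM + 1 on log scales, with the line of equality and dotted lines at 2-fold. The 9 muscle and 11 pancreas genes at least 2-fold apart lie above the upper dotted line, and the 28 cell cycle genes (the proliferation list) lie just below equality.

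Most whole lists differed by small amounts between the livers. Of 40 lists with enough members, 17 had a median log2 ratio outside the middle 95% of matched random lists, where 2 would lie outside by chance if genes were independent. The muscle median was 3.45 (10 members, all higher in pup 2) and the pancreas median 2.20 (14 members, all higher), both at percentile 100 of the random lists. The 28 cell cycle genes were all lower in pup 2, with a median of -0.20 against -0.086 to 0.022 in random lists. Glycolytic genes had a median of -0.22 with 14 of 15 lower, replication-dependent histone genes -0.22 with 38 of 50 lower, and erythroid genes -0.10 with 24 of 26 lower. Mast cell and basophil genes (-0.25), gluconeogenesis (-0.11), metal and vitamin handling (-0.11), fatty acid oxidation (-0.073) and long noncoding RNAs (-0.14) also lay below. Above were mitochondrial mRNAs (0.17), adult cytochrome P450 genes (0.15), hepatocyte transcription factors (0.15), urea cycle and amino acid genes (0.084), clock genes (0.083) and acute phase genes (0.068). All 6 of these positive medians turned negative with spike-in scaling, which moved the median of all genes by -0.21, while their percentiles among random lists were 99.6 or more. With TMM or median-of-ratios scaling 23 lists lay outside, and with spike-in scaling 16. After a correction for effective length and GC content, chosen after seeing the data, 15 lists lay outside, 14 of them among the 17; fatty acid oxidation, long noncoding RNAs and acute phase genes no longer did.

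**Figure D4:**
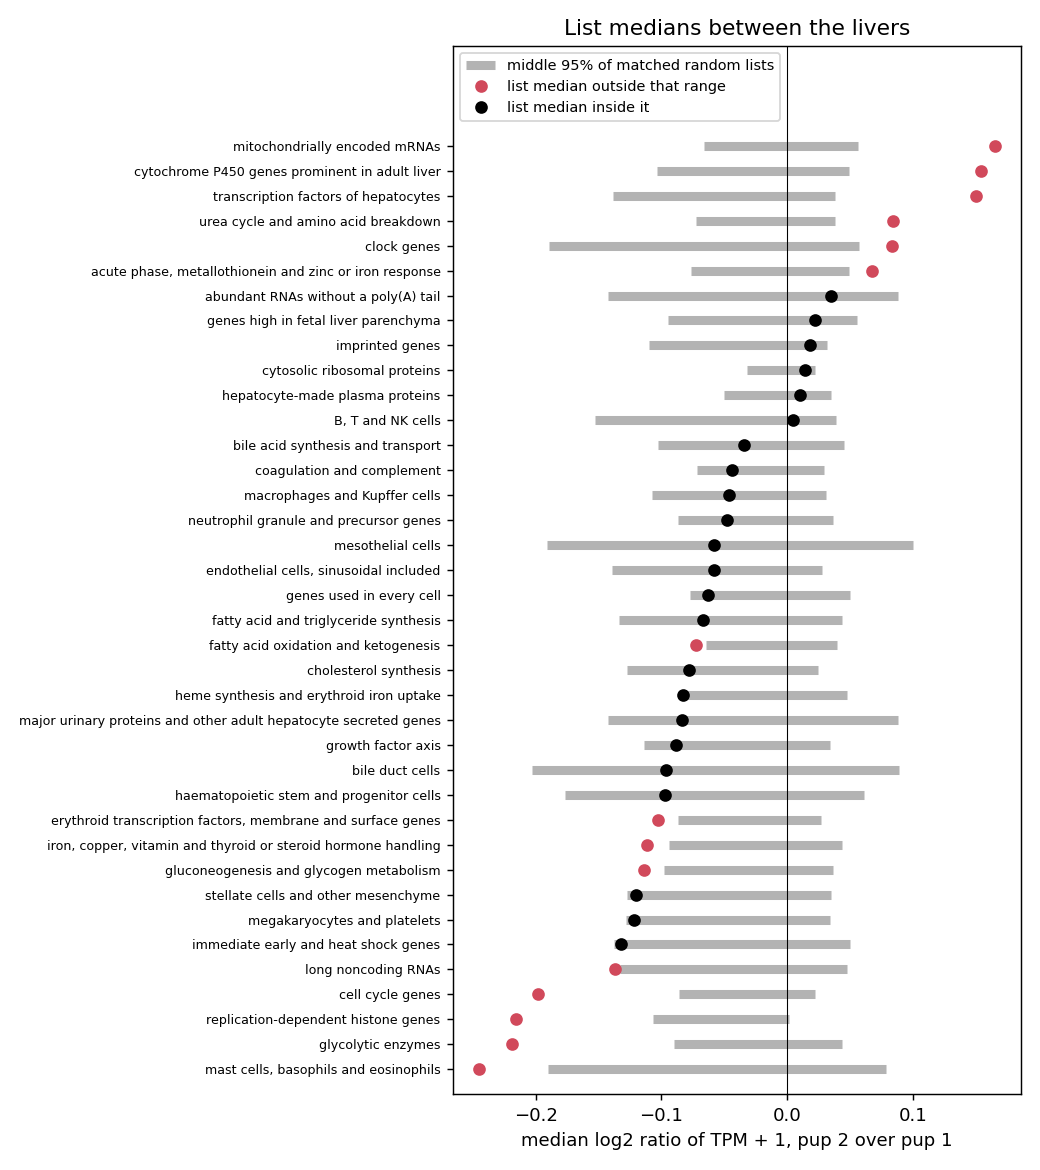
Median log2 ratio of TPM + 1, pup 2 over pup 1, for the gene lists other than muscle and pancreas; grey bars span the middle 95% of 10000 matched random lists and red points lie outside it. Cell cycle and glycolytic genes lie lowest with histone and mast cell genes (-0.20 to -0.25), and mitochondrial mRNAs highest (0.17, or -0.079 with spike-in scaling).

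The most abundant transcript of a gene was mostly shared. Among 6002 genes with at least 2 transcripts and a mean TPM of 5 or more, the livers had the same most abundant transcript in 5605, or 93.4% (exact 95% binomial interval 92.7% to 94%). It held a median of 73.8% of the gene's TPM in pup 1 and 74.5% in pup 2. Trf-201 held 71.1% and 69.6% of Trf, Apoa1-201 99.6% in both, Apoa2-201 59.2% and 59.1% of Apoa2, and Apoe-209 85.6% in both. Among the most abundant genes whose leading transcript differed, most were near an even split. For Hba-a1 the leading transcript held 51% in pup 1 and another 50.6% in pup 2, and Rps14, Igfbp4, Rpl29, Romo1, Psma3, Hnrnpf and Gm6472 were also divided. Serpina3m showed a larger change, with Serpina3m-201 at 76.2% in pup 1 and 46.2% in pup 2, within a family of similar genes.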

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

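The tests of depth and of shared reads below were chosen after the result was seen; the test of carried-over tissue was written before. Rows outside the comparisons held counts above the floor of 3 counts. The tRNA rows drew 17.3 expected counts in pup 1 and 8 in pup 2. Ensembl rows without a symbol in the reference drew 42120 expected counts in pup 1 and 42887 in pup 2.

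The muscle and pancreas genes formed the clearest difference between the littermates. Of the 33 members of these lists, 0 belong to another list, and in pup 1 a TPM of 1 or more was reached by 8 muscle and 2 pancreas genes. A difference in depth is argued against, since the expected count total of pup 2 was 0.984 times that of pup 1. For reads shared with related genes, 16 of the 24 members at a mean TPM of 1 or more had whole expected counts in both livers, with no trace of divided reads. The other 8 had fractions. Among these, the authors' credible intervals, which cover read assignment, did not overlap for Ckm, Tnnc2, Myh8, Try4, Try5, Try10 and Prss1. For Ckm they were 2.89 to 3.93 TPM in pup 1 and 61.8 to 66.3 TPM in pup 2. This argues against shared reads as the source of the difference in these genes. Single values of the trypsinogens stay uncertain. For Amy2a5 the intervals overlapped (0.634 to 27.9 and 1.02 to 48 TPM), so shared reads stay open there. Carried-over tissue needed several members of a list to be present and over 2-fold apart, and 22 were, 9 of muscle and 13 of pancreas. They were counted at a TPM of 1 or more in a liver, without the credible intervals. These genes are the pattern itself, so the count cannot tell its sources apart. Muscle and pancreas fragments taken with the liver of pup 2 may be a source. Expression by cells within the liver was not tested and stays open.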

How the results depend on the processing

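The correction for effective length and GC content and the count without the muscle and pancreas lists were chosen after seeing the data. With 2 livers, each liver alone lies within 1 SD of the mean by construction, so leaving 1 out shows nothing about stability. Of the other alternative values, those with a spread stayed within it 356 times, moved beyond it 347 times and changed sign 6 times. The spread was not always a replicate or counting spread. For list medians it was the SD of the medians of matched random lists, and all 6 sign changes were of list medians. The spreads of Pearson's r and of the coefficient of variation were not between livers either. For these values the tally does not describe variation between animals. Counts without a spread were within 1.5 times of the main count 26 times and beyond it 4 times. The number of detected genes was 8038 at 5 TPM. The share of the 10 top genes was 20.9% of expected counts, 28.2% without mitochondrial genes, 26.4% by posterior mean TPM and 29.6% over protein-coding genes. Plasma proteins held 20.2% of expected counts, 17.1% without mitochondrial genes and 19% without globins; adult globins 6.3% and 15.2% under the first 2 of these, and mitochondrial mRNAs 2.32% of expected counts and 4.64% without globins. The coefficient of variation was 0.135 with no filter. Pearson's r was 0.981 with 0.1 TPM added, 0.988 at a mean TPM of 1 or more, 0.996 with TMM-scaled counts and also by posterior mean TPM. The genes at least 2-fold apart numbered 36 at a mean TPM of 5 or more, 186 at 1.5-fold and 159 without the credible interval; higher calls made up 68.3% and 65.4% of the last 2 and 79% with spike-in scaling, against 90%. The share of spike-ins was 7.46 TPM, and no spike-in reached 100 counts. The shared leading transcript was 95.3% of genes at 20 TPM and 99.9% where it held 60% or more.

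With spike-in scaling the list medians changed sign for hepatocyte transcription factors (-0.056), cytochrome P450 genes (-0.086), urea cycle genes (-0.13), acute phase genes (-0.16), mitochondrial mRNAs (-0.079) and clock genes (-0.085). The glycolysis median was -0.16 with TMM, -0.46 with spike-ins and -0.17 with median-of-ratios; the cell cycle median was -0.13, -0.44 and -0.15, and -0.16 after the length and GC correction. The muscle median was 4.06 with 0.1 TPM added, 3.84 with TMM, 3.22 with spike-ins, 3.56 without globins and mitochondrial genes, 3.83 with median-of-ratios, 3.92 for members at 5 TPM and 3.52 after the correction. The pancreas median was 4.79, 1.77, 2.01, 2.42, 1.77 and 3.97 under the first 6 of these. Spike-in scaling divided every TPM of pup 2 by the same factor, 1.18, so the sign changes follow from that factor. Its counting interval was 0.956 to 1.47, which includes 1. The TMM and median-of-ratios medians were taken on log2(CPM + 1) in place of log2(TPM + 1), so unit and scaling changed together. The cause of the changes under the other settings was not tested. Spike-in scaling rests on 163 and 190 counts.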

Other observations

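The tests of the cell cycle list below were chosen after the result was seen; the test of oligo-dT priming was written before. Genes of a further organ were noticed after their values were seen. Surfactant protein Sftpc, made in lung, was at 1.52 TPM in pup 1 and 12.1 TPM in pup 2, and the airway secretory gene Scgb1a1 at 0.75 and 3.26 TPM. Neurons gave no such signal, since all 12 genes of that list stayed below 1 TPM in both livers.

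Cell cycle genes were lower in pup 2, with all 28 below pup 1. The log2 ratio between the libraries was also lower for longer genes, with a Spearman rho of -0.218 for effective length and 0.0543 for GC content over 12646 genes, which are not independent. This trend is argued against as the whole cause, since the median was -0.16 after its removal, below the range of -0.054 to 0.051 in random lists. Dilution by other tissue is argued against, since the median of the plasma protein list lay 0.21 above that of the cell cycle list. A lower share of blood-forming cells may contribute, with erythroid (-0.10) and mast cell and basophil (-0.25) medians below the middle 95% of random lists. Heme synthesis (-0.083) and megakaryocyte (-0.12) medians lay inside it, the latter only before the length and GC correction. Also inside were neutrophil (-0.048), macrophage (-0.047), stem and progenitor (-0.097) and lymphoid (0.0049) medians. The adult globin median was 0.026, so a lower share cannot be told apart from a change within hepatocytes or other cells. No other biological explanation was tested, as both livers belong to 1 group.

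Oligo-dT priming would leave RNAs without a poly(A) tail at low levels. These RNAs held 2.33% of TPM (0.402% of expected counts), above the 1% foreseen for priming on poly(A) and below the 10% foreseen against it. The median of the replication-dependent histone genes was 10.3% of that of cell cycle genes in pup 1 and 11.9% in pup 2, near the bound of 10%. The values cannot be told apart from those of priming without selection, as most of the list's TPM came from the 7SL copies. Members below the size limit of the input RNA, such as Rnu11 and Rny1, also tell nothing about priming.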
